A study of Streptomyces lividans with 6 samples.

How the data were processed

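RNA-seq was carried out on 6 libraries of Streptomyces lividans TK24, 3 from the PM and 3 from the SM regulatory strain, after 84 h of growth. Per the labels' protocols, ribosomal RNA was removed with a Ribo-Zero kit and libraries were made with an Illumina TruSeq kit from total RNA. HISAT2 and FastQC 0.11.4 are named by the submitters' processing notes. The genome build, the annotation, the program that counted reads, the use of strand and the program behind the authors' comparison were not given in the sources used here.

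The authors deposited raw counts per feature and library, whole numbers by the values, in columns that per the file headers hold counts. The authors deposited TPM values beside them, per the file headers, which by their definition are scaled for feature length. The authors' deposited log2 fold change is SM over PM, per the file headers. The authors' deposited p-value and adjusted p-value stand beside it, and their test was not given. In the authors' deposited table, the significant mark was on the 165 features with p under 0.05 and an absolute log2 fold change of 1 or more, so adjusted p was not part of it. Deposited FastQC reports of each mate hold read numbers, read length, GC content, quality, duplication, adapter content and overrepresented sequences, per the file headers. Overrepresented sequences were compared with an SpCas9 guide RNA scaffold sequence written from general knowledge.

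The table in hand may be part of a larger one. Among the 100 smallest p-values, 96% gave a whole rank (within 0.001) when the authors' deposited adjusted p-values were read as Benjamini-Hochberg values over 10610 features, while 8041 are in hand. The deposited TPM columns fell short of the full TPM sum by 0.333 ± 0.0450% in PM and 1.21 ± 0.0579% in SM (SD, n = 3). The counts used here leave out any such features. The ratio of count to TPM, which would be fixed by a constant feature length, varied between libraries with a median CV of 0.547% and a largest CV of 9.54% among 6159 features with at least 50 counts in every library. The counts were used as whole counts, and whether they were rounded estimates is unknown. Overlapping features, near-identical copies and antisense partners cannot be told apart in them.

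Libraries were assigned to strain by the genotype in their labels and numbered as replicates by their titles. Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM normalization and the robust quasi-likelihood test, strain being the only term. P-values were adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05, and direction is SM over PM. CPM values are normalised by TMM. With 6130331 to 7799521 counts per library, a feature at 1 CPM rests on about 6 to 8 counts. Replicates of each strain differed beyond sampling noise (chi-square per degree of freedom from 8.81 to 30.0 over the 6 pairs), so no pair looked like 1 library deposited more than once, and each was counted. This does not show that they came from separate cultures.

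The edgeR step was tested on simulated counts with 200 changed genes drawn, for SM against PM and 7332 features tested. It recovered 33 of 50 genes changed 1.5-fold, 33 of 50 changed 2-fold, 41 of 50 raised 4-fold and 38 of the 47 tested among those lowered to 0.25. It made 15 false calls beside these, and 0 calls when no gene was changed.

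Before the data were examined, 35 gene lists were defined by product text, gene symbol or SCO number, with the tests, the alternatives and the rule for named genes. Products and SCO numbers were not used here, so members were matched by symbol alone, and 10 lists had no member. Lists with 5 or more tested members were tested with camera (preset correlation 0.01, and estimated) and fry in limma 3.58.1, adjusted over the 14 lists. The naming rule takes hrdB, the 12 largest rises and 12 largest falls among calls without overlap and with at least 10 CPM in the higher strain, and up to 4 members with the smallest p of each list, printed for called lists and those the title bears on. Its condition on products could not be applied. Because the files do not pair most tags with names, 2 tags that rose and 2 that fell are printed with their levels. Further tags that fell outside the stretch were named after their values were seen, with fold changes only. Members of other lists and the called genes with symbols were named after their values were seen.

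Tag order was taken from the locus tag numbers, which give an order but no coordinates. Runs were formed from calls of one direction separated by at most 3 tested genes, a definition set after the data were seen, and compared with 10000 random orders. The ends test used 6247 tags up to number 37500, a limit also set after the tags were seen, and left out 178 tested tags. Well-counted genes are those with a mean log2 CPM of 5 or more. Differences between strains in library measures were tested with exact two-sided permutation tests, where 3 against 3 cannot give a p under 0.1. Alternatives were other normalizations, DESeq2 1.42.0, limma-voom, other filters, a replicate block, leaving out each library, and other thresholds. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels and matplotlib 3.10.9 was used for the rest.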

Results

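RNA was sequenced from cultures of Streptomyces lividans TK24, a soil bacterium with a linear chromosome that is used as a host for antibiotic clusters and secreted proteins. The labels give 2 groups, called the PM regulatory strain and the SM regulatory strain, with 3 libraries each, all from cultures grown for 84 h. The series title concerns hrdB, the gene of the principal sigma factor, and secondary metabolism. What the letters PM and SM stand for was not given in the sources used here. The deposited counts summed to 7000249, 7229739 and 7799521 in the PM libraries and to 7562434, 7263337 and 6130331 in the SM libraries. These totals were spread over 8041 features, of which 6841 carried locus tags beginning with SLIV_RS and 1200 were named as predicted RNAs. The files paired 632 features with a gene symbol and did not pair the others with names. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

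Few features were called as different between the SM and PM strains, and the largest single block of calls was a stretch of neighbouring genes lower in SM. Before adjustment 1078 features had p under 0.05 (edgeR), so features that were not called are not shown to be unchanged. Of 7466 features tested, 95 differed, with 39 higher and 56 lower in SM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per strain). Over 2-fold differences made up 56 of the 95, with 18 higher and 38 lower in SM. All 95 had no overlap between the values of the 3 SM and the 3 PM libraries. Among all features tested, 1573 (21.1%) had no such overlap, where chance gives 10% for 3 against 3. The median absolute log2 fold change over all tested features was 0.13. Predicted RNAs made up 22 of the calls, 8 higher and 14 lower in SM, and 3 of the calls carried a gene symbol. DESeq2 called 551 features on the same counts, 289 higher and 262 lower in SM. The number of features higher in SM was 20 with a replicate block and 59 with a minimum of 10 CPM in 3 libraries.

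**Figure D1:**
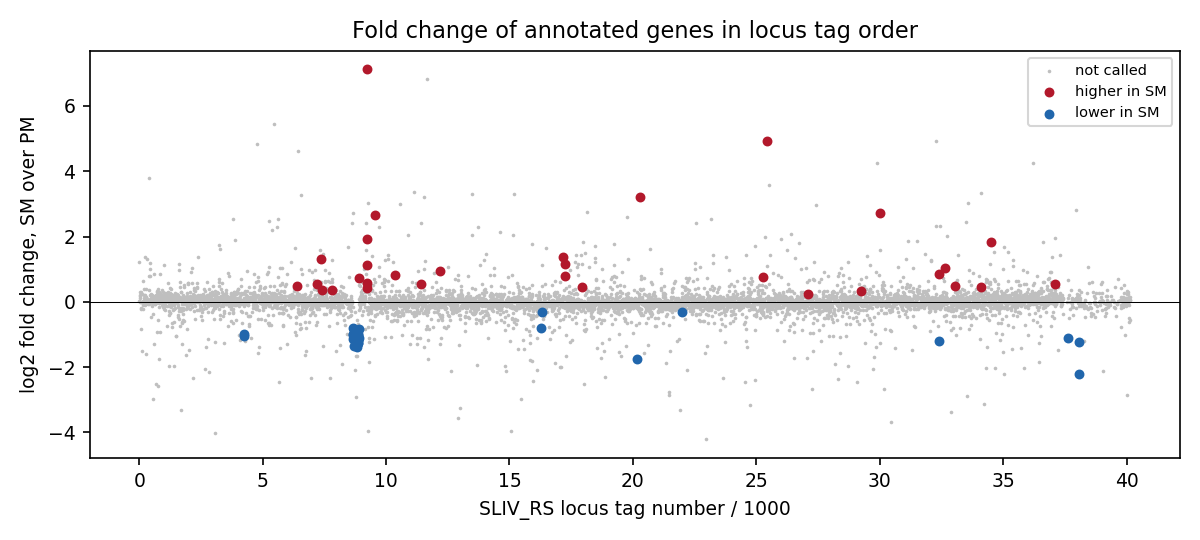
Log2 fold change of SM over PM (vertical axis) for each of the 6425 tested features with an SLIV_RS locus tag, against the tag number divided by 1000 (horizontal axis, as an order and not as coordinates). Grey points were not called, red points were higher and blue points lower in SM at an adjusted p under 0.05 (edgeR). The 32 lower genes of the stretch form the dense blue group below 0 near the left of the plot.

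The stretch ran from SLIV_RS08650 to SLIV_RS08900 in locus tag order and held 42 tested genes. Of these, 32 were lower in SM, 10 were not called and 0 were higher. Among its 34 genes with a mean log2 CPM of 5 or more, the median log2 fold change was -1.08, with quartiles of -1.17 and -0.98, so that PM levels were 2.12-fold those of SM. At the ends of the stretch, SLIV_RS08650 fell from 116 ± 9.16 normalised CPM in PM to 66.4 ± 6.38 in SM (SD, n = 3), a log2 fold change of -0.81 ± 0.10 (SE, edgeR adjusted p = 0.00709). SLIV_RS08900 fell from 267 ± 10.1 to 124 ± 5.63 normalised CPM (SD, n = 3), a log2 fold change of -1.10 ± 0.06 (SE, edgeR adjusted p = 9.07e-05). These 2 tags were chosen after their values were seen, because they bound the stretch. The call of SLIV_RS08650 was lost with a replicate block (edgeR adjusted p = 0.0508). The number of calls in the stretch lay between 27 and 35 over all 15 fits of the comparison.

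One member of the stretch carried a symbol and was called: cbiQ, named for the membrane component of a cobalt uptake transporter. Its level fell from 49.4 ± 6.51 normalised CPM in PM to 21.8 ± 3.73 in SM (SD, n = 3), a log2 fold change of -1.18 ± 0.17 (SE, edgeR adjusted p = 0.0175). The call of cbiQ was lost in 4 of 14 alternative fits, those without PM replicate 1, PM replicate 3 or SM replicate 1 and that with a replicate block, where its edgeR adjusted p lay between 0.0639 and 0.0862. One of the 34 well-counted genes stood apart from the others, with a log2 fold change of 0.51 ± 0.16 (SE, edgeR adjusted p = 0.223).

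Relative to the median TPM of well-counted genes in the same library, the stretch stood at 1.86 ± 0.0578 in PM and at 0.874 ± 0.0146 in SM (SD, n = 3). The 63 well-counted genes among the 50 on either side stood at 1.54 ± 0.0342 in PM and at 1.63 ± 0.0423 in SM (SD, n = 3), and their median log2 fold change was 0.04. All 3 PM libraries lay above all 3 SM libraries for the stretch (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). The stretch was picked by its lower calls in these same libraries, so this separation was fixed in advance and is no test.

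**Figure D2:**
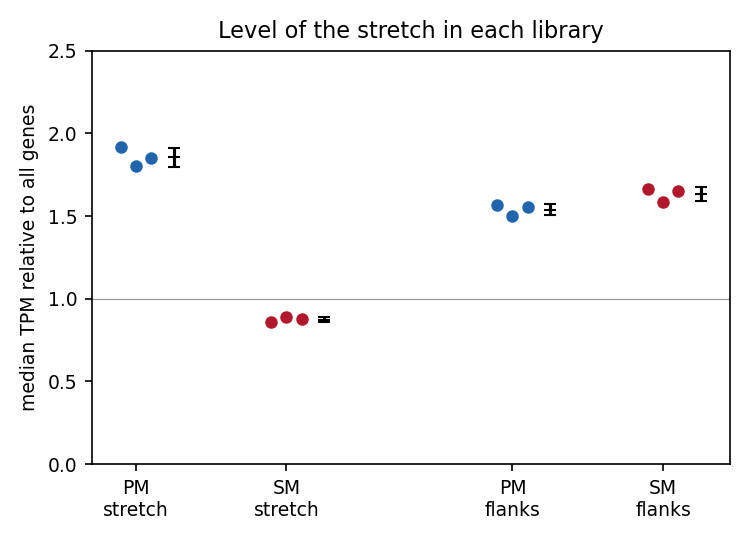
Median TPM of the stretch and of its flanking genes, each divided by the median TPM of all well-counted genes of the library (vertical axis, no unit), for the PM (blue) and SM (red) strains. Points are the 3 libraries, and the bars beside them give the mean and SD. The stretch stood at 1.86 in PM and 0.874 in SM, while the flanks stood at 1.54 and 1.63.

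Apart from the tagged genes of the stretch, 63 features differed, of which 24 were lower in SM. These 24 included 14 predicted RNAs, which have no place in the tag order and could not be placed inside or outside the stretch. Of the 14, 12 had log2 fold changes between -1.3 and -0.8, near that of the stretch, and 9 had names numbered within 30 of each other. Of all 24, 18 lay in that range, so tagged genes outside the stretch fell by a like factor too. They included SLIV_RS04235 and SLIV_RS04240, which have consecutive tags, at -0.98 and -1.04. SLIV_RS37630 and SLIV_RS38085, at -1.11 and -1.23, have tags past the limit of the ends test. These 2 were counted as outside the stretch by tag number alone. The 39 higher ones included 5 in a short run of 6 tested genes, which had a median log2 fold change of 0.86. That run included the called feature with the largest rise, SLIV_RS09235, which had 7, 0 and 0 counts in the PM libraries and 296, 321 and 331 in the SM libraries. Its fitted log2 fold change was 7.13 ± 0.77 (SE, edgeR adjusted p = 0.00342) and rested on the counts of PM replicate 1. Without that library, with both remaining PM libraries at 0, the fitted value was 11.39, which is no measure of the size of the change. The call of SLIV_RS09235 was lost under limma-voom (adjusted p = 0.178) and with a replicate block (edgeR adjusted p = 0.0678). The next, SLIV_RS25455, had 10, 0 and 15 counts in PM and 217, 201 and 268 in SM, with a log2 fold change of 4.92 ± 0.81 (SE, edgeR adjusted p = 0.0336). Its call was lost in 7 of 14 alternative fits: limma-voom, the replicate block and 5 of the 6 fits that left out a library, all but that without PM replicate 2. Adjusted p in these 7 fits lay between 0.0601 and 0.289 (edgeR or limma-voom), and the log2 fold change was 5.57 without PM replicate 3. Among called features with at least 10 CPM in the higher strain, the 12 largest rises had log2 fold changes from 1.82 to 7.13 and included 5 predicted RNAs. The 12 largest falls among the same called features had log2 fold changes between -2.21 and -1.20, and 6 of them were tagged genes of the stretch. Features that were not called are outside both rankings.

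Enzymes of sugar metabolism gave the other 2 called symbols, with changes well under 2-fold. The gene treZ, named for the enzyme that releases trehalose from maltooligosyl trehalose, rose from 114 ± 3.10 normalised CPM in PM to 147 ± 0.753 in SM (SD, n = 3). Its log2 fold change was 0.36 ± 0.06 (SE, edgeR adjusted p = 0.0253). The gene galT, named for the uridylyltransferase of galactose breakdown, fell from 560 ± 25.3 to 454 ± 14.6 normalised CPM (SD, n = 3). Its log2 fold change was -0.30 ± 0.05 (SE, edgeR adjusted p = 0.0220). The call of treZ was lost in 8 of 14 alternative fits, namely library totals only, the replicate block and each of the 6 fits without a library (edgeR adjusted p from 0.0672 to 0.134). The call of galT was lost in 6, the replicate block and the fits without PM replicate 1, PM replicate 2 or any 1 SM replicate (edgeR adjusted p from 0.0503 to 0.0841).

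The series title names hrdB, and 0 features in hand carried that symbol, so its values could not be identified. It may be among the tested features without a symbol, called or not, so no result is given for it. The sigma factor list had 3 tested members, and 0 were called over all genes or adjusted over the list alone (edgeR; 0 with p under 0.05 before adjustment). The log2 fold change was 0.18 ± 0.13 for sigE, a sigma factor of the cell envelope stress response. It was -0.16 ± 0.14 for sigJ and -0.27 ± 0.28 for whiG, the sigma factor of early sporulation (SE, edgeR adjusted p = 0.623, 0.687 and 0.746).

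Secondary metabolism, the other subject of the title, was represented by 2 clusters with matched symbols. In the cluster of actinorhodin, a blue polyketide pigment, 3 genes were tested and 0 were called over all genes or adjusted over the list alone. The log2 fold change was -0.26 ± 0.18 for actVB, 0.28 ± 0.44 for actVA and 0.03 ± 0.08 for actII (SE, edgeR adjusted p = 0.603, 0.847 and 0.921). In the coelimycin cluster, scbC, scbB and scbA had log2 fold changes of 0.16 ± 0.11, -0.09 ± 0.13 and 0.05 ± 0.15 (SE, edgeR adjusted p = 0.575, 0.820 and 0.937). Of these 3 scb genes, 0 were called over all genes or adjusted over the list alone. The gene scbA is known for synthesis of butyrolactone signals. Of the 4 terpene and hopanoid genes tested, 0 were called, and crtI of carotenoid synthesis had the smallest p (log2 fold change 0.26 ± 0.08 (SE), edgeR adjusted p = 0.214, 0.0532 adjusted over the list alone). No symbol in hand matched the lists for undecylprodigiosin, the calcium-dependent antibiotic or polyketide and nonribosomal peptide synthetases. Genes of these lists may be among the features without a symbol, called or not, so these lists were not tested.

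No member of any of the 25 lists with a tested gene was called over all genes (edgeR). Adjusted over the list alone, 13 members of 9 lists passed. In the list of DNA replication and repair, 4 of 19 tested members passed on that footing, all lower in SM. The symbols matched to this list included dnaK and dnaJ, which are names of chaperone genes and were counted in the chaperone list as well. The 4 that passed were the replicative helicase gene dnaB (log2 fold change -0.65 ± 0.12), the excision repair genes uvrB (-0.40 ± 0.10) and uvrC (-1.04 ± 0.30) and the helicase gene recG (-0.35 ± 0.09, SE). Over all genes, edgeR adjusted p was 0.0630 for dnaB, 0.140 for uvrB, 0.185 for uvrC and 0.154 for recG. This list had the smallest camera p of the 14 lists with 5 or more tested members (limma's camera, p = 0.0114, adjusted p = 0.160), and adjusted p = 0.768 with an estimated correlation. It was called by camera without PM replicate 3 (adjusted p = 0.0181) and with a minimum of 10 CPM in 3 libraries (adjusted p = 0.0470), where adjusted p with an estimated correlation was 0.834 and 0.599.

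The other 9 members that passed when adjusted over the list alone came from 8 lists. Lower in SM were secY of the Sec translocon (1 of 10 in its list, log2 fold change -0.60 ± 0.11), clpX of a Clp protease (1 of 8, -0.47 ± 0.10) and ftsI of septal wall synthesis (1 of 9, -0.19 ± 0.05; SE). Their edgeR adjusted p over all genes was 0.0637, 0.0950 and 0.116. Both tested genes with an ATP synthase symbol passed, atpD at -0.75 ± 0.28 and atpB at -1.17 ± 0.45 (log2, SE). So did rpoB, the single tested gene with an RNA polymerase core symbol, at -0.50 ± 0.21 (log2, SE). Other genes of these complexes may be among the tested features without a symbol, so these values do not describe the complexes. Over all genes their edgeR adjusted p was 0.295, 0.301 and 0.327. The siderophore synthesis gene desA passed at -0.28 ± 0.08 (1 of 3). The translation initiation factor gene infB (1 of 6) and the nitrate reductase gene narI (1 of 13) were higher in SM, at 0.30 ± 0.06 and 0.41 ± 0.09 (log2, SE). Over all genes, the edgeR adjusted p was 0.165 for desA, 0.0651 for infB and 0.116 for narI. The symbol narI was carried by 3 tested features, and the other 2 did not pass on either footing, at 0.10 ± 0.05 and -0.16 ± 0.20 (log2, SE, edgeR adjusted p = 0.438 and 0.792).

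Of the 14 lists tested as sets, 0 were called by camera, 1 had a camera p under 0.05 before adjustment, and 1 was called by fry. The last was cell wall synthesis and division, lower in SM on balance (limma's fry, adjusted p = 0.0440, median log2 fold change -0.10). Its camera adjusted p was 0.502, and adjusted p = 0.768 with an estimated correlation. The 36 ribosomal protein genes tested had a median log2 fold change of -0.03, with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.528). Lists of NADH-quinone oxidoreductase, the tricarboxylic acid cycle, glycolysis, oxidative stress defence, phosphate uptake and aerial growth and sporulation had 0 members that passed on either footing. Their median log2 fold changes were -0.06, 0.02, 0.01, 0.01, -0.06 and -0.08, and their camera adjusted p lay between 0.694 and 0.852. The nitrogen assimilation list had a median of 0.07 (camera adjusted p = 0.694), chaperones and Clp proteases -0.13 (0.528), Sec and Tat secretion -0.11 (0.502) and translation factors 0.00 (0.708). The median and mean differed in sign for phosphate uptake, nitrogen assimilation, glycolysis, the tricarboxylic acid cycle and the anti-sigma factor list; camera's direction followed the mean for glycolysis and the anti-sigma factors and the median for the others. The anti-sigma list was called 0 times among 6 members (median -0.02, camera adjusted p = 0.864). Those members were rsmI, rsmH, rsmA, rsmG, rsgA and rsuA. The rsm symbols are names of ribosomal RNA methyltransferases, so the list as a set gives no result about anti-sigma factors. Whether rsgA and rsuA encode anti-sigma factors could not be checked without products. Their log2 fold changes were 1.47 ± 1.40 and -0.14 ± 0.15 (SE, edgeR adjusted p = 0.723 and 0.751).

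Smaller lists were described by their genes. The 4 tested genes of cytochrome oxidases and the bc1 complex had 0 calls and a median log2 fold change of 0.11. The single tested genes of gas vesicles (gvpA, 0.30 ± 0.59) and fatty acid synthesis (fabG, -0.19 ± 0.12) were not called (log2, SE, edgeR adjusted p = 0.891 and 0.571). The 5S ribosomal RNA gene rrf stood at 103 ± 8.12 normalised CPM in PM and 157 ± 78.7 in SM (SD, n = 3), with a log2 fold change of 0.60 ± 0.31 (SE, edgeR adjusted p = 0.446). The value of rrf in SM rested on SM replicate 3, at 247 normalised CPM against 98.1 and 127 in the other 2, and without it the log2 fold change was 0.12 ± 0.13 (SE, edgeR adjusted p = 0.808).

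Calls of the same direction lay next to each other more often than in a random order, mostly within the stretch. Among 5396 pairs of consecutive tags, 22 pairs were called in the same direction, where the median of 10000 random orders was 0 and the most was 4 (permutation p = 0.0001, the smallest these orders can give). The stretch held 17 of the 22, and with its genes left out 5 pairs remained, against at most 3 in random orders (permutation p = 0.0001). Calls over 2-fold gave 9 such pairs. The stretch was the longest run, with 32 calls against at most 4 in random orders (permutation p = 0.0001). Genes lower in SM were rarer in the outer 20% at either end of the tag order, with 3 of 2498 against 36 of 3749 in the middle (Fisher's exact test, two-sided, odds ratio 0.124, p = 9.33e-06). With the calls of the stretch set aside and its genes kept as not called, these numbers became 3 and 4 (Fisher's exact test, odds ratio 1.13, p = 1). With wider ends of 4164 tags, the ends held the stretch, with 35 lower genes against 4 of 2083 in the middle, and the odds ratio turned to 4.41 (Fisher's exact test, p = 0.00172). Genes higher in SM numbered 9 of 2498 at the ends and 22 of 3749 in the middle (Fisher's exact test, odds ratio 0.613, p = 0.271). With the wider ends their odds ratio also turned, to 2.61 (26 of 4164 against 5 of 2083, Fisher's exact test, p = 0.0541), so the direction of both depended on where the ends were cut.

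The authors' deposited table marked 165 features as significant, 73 higher and 92 lower in SM, and 82 of these had an adjusted p of 0.05 or more in the authors' deposited table. By that adjusted p alone, 213 features of the authors' deposited table passed 0.05, 110 higher and 103 lower in SM. Of these 213, 93 were also called here (43.7%), all in the same direction, and 2 calls made here were not among them. Of the 83 with an over 2-fold change in the authors' deposited table, 61 were called here (73.5%). Across 7466 features, log2 fold changes of the authors' deposited table and of the edgeR fit had a Spearman's rho of 0.989, where features are not independent replicates.

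The spread of levels between features was narrow in every library. Median TPM lay between 93.5 and 104 over the 6 libraries, and the 75th percentile was 3.21 to 3.53 times the 25th. The 38 ribosomal protein genes had a median TPM that was 1.21 ± 0.0588 times the median of all features in PM and 1.17 ± 0.0905 times in SM (SD, n = 3; exact permutation test, two-sided, p = 0.7). The 10 most abundant features took 4.54 ± 0.787% of counts in PM and 7.29 ± 2.87% in SM (SD, n = 3; exact permutation test, p = 0.1, Benjamini-Hochberg 0.2 over 16 measures). SM replicate 3 had the highest share, 10.6%.

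**Figure D3:**
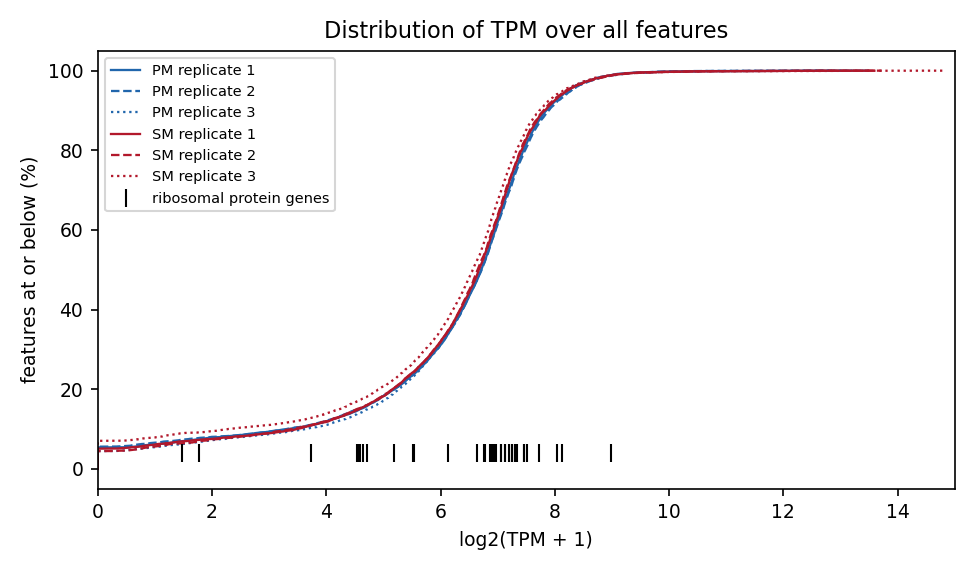
Share of the 8041 features (vertical axis, percent) with a log2(TPM + 1) at or below the value on the horizontal axis, for each of the 6 libraries. Black ticks near the bottom mark the mean level of each of the 38 ribosomal protein genes. The curves of PM (blue) and SM (red) rise steeply around the medians of 93.5 to 104 TPM, and SM replicate 3 (red, dotted) lies slightly to the left of the others.

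Sequencing depth was alike in the strains, while duplication and adapter content separated them. Each library had between 7239296 and 8874396 read pairs of 151 bases (exact permutation test between strains, p = 0.8). Deduplicated reads made up 49.6 ± 1.41% of read 1 in PM and 46.5 ± 0.853% in SM (SD, n = 3). Adapter content at the last position of read 1 was 13.5 ± 1.46% in PM and 18.5 ± 2.48% in SM (SD, n = 3). All 3 SM libraries lay to the same side of all 3 PM libraries for both measures (exact permutation test, two-sided, p = 0.1 each, Benjamini-Hochberg 0.2). GC content of read 1 was 69 or 70% in every library.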

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

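All tests of explanations in this part were chosen after the results were seen, except the count of other splits of the libraries.

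A sequence that matches a guide RNA scaffold was listed in data outside the gene counts. In the FastQC reports, a 50-base sequence was the reverse complement of part of an SpCas9 guide RNA scaffold sequence written from general knowledge and not taken from a source of the study, so its identity is unchecked. It was listed in read 2 of all 6 libraries, at 0.115 to 0.152% of reads. That made 10147 to 11680 reads per library. It is given here as a signal in data that no comparison used, and its listing is no test, since FastQC lists only sequences above a minimum share. The mean was 0.132 ± 0.0144% in PM and 0.132 ± 0.0178% in SM (SD, n = 3; exact permutation test, p = 1). The labels used here mention no guide RNA. A further 50-base sequence with no assigned source was listed in read 1 of the 3 SM libraries, at 0.175 to 0.593%, with the highest share in SM replicate 3. It was not listed in read 1 of the PM libraries, where its share was not given. In read 2, this sequence or one overlapping it was listed only for SM replicate 3, at 0.236% (17093 reads). The deposited TPM columns fell short of their full sum by 1.21 ± 0.0579% in SM and 0.333 ± 0.0450% in PM (SD, n = 3; exact permutation test, p = 0.1).

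The narrow spread of TPM values was weighed because it bears on every fold change. Ribosomal protein genes, which are among the most abundant messengers of growing bacteria, stood at 1.19 times the median of all features (mean of 6 libraries, range 1.08 to 1.26). A candidate explanation is that most reads came from genomic DNA, which would give such a value, as would fewer ribosomal protein messengers in old cultures. Against it, 360 to 568 features per library had 0 counts, and 241 (7.04%) of the 3421 tagged genes of at least the median relative length lay under 10% of the median TPM, which mostly genomic reads would not leave unless reads were assigned elsewhere, so it stays open. Division of reads between overlapping features would leave longer genes, which share less of their length, with a wide spread. The 75th percentile of those longer genes was 2.40 times the 25th, narrower than the 3.18 of all tagged genes. That value fell short of the bound set for this explanation and was not past the bound set against it, so this explanation also stays open. So do uniform messenger levels in 84 h cultures, since levels of genes with consecutive tags had a Spearman's rho of 0.151 across 949 pairs (bootstrap 95% interval 0.0873 to 0.217), which is above 0 and decides for neither.

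The lower stretch in SM was weighed next. A chance order of the calls is argued against by the random orders (permutation p = 0.0001, the smallest they can give), and a length bias by genes of like relative length elsewhere, whose median log2 fold change was 0.00978. A difference in copy number of the stretch between the strains may give such a shared fold, and the gene-to-gene SD of its log2 fold changes beyond their errors was 0.290 over the 34 well-counted genes, between the bounds set for and against it after these values were seen (0.25 and 0.5). That SD was 0.103 without the 1 gene over 0.7 from the median, a choice made after its value was seen. The 39 features higher in SM gave 1.43. They were picked by their calls and included features near 0 counts in PM, such as SLIV_RS09235, so 1.43 is no reference for a block of genes. A regulator acting on every gene of the stretch could also give a shared fold such as the 2.12-fold difference, which was not tested. It and a copy number difference cannot be told apart from these counts, and neither can a gain in PM from a loss in SM.

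Other splits of the 6 libraries into 3 against 3 were compared with the real one. The real split gave 95 calls and the highest of the other 9 splits gave 0 (375 with p under 0.05 before adjustment, against 1078). With 10 splits in all, of which 1 gave as many calls, the share cannot fall under 0.1, which is too few splits for a test at 0.05.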

How the results depend on the processing

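Counts outside the stretch (tagged genes of the stretch left out, predicted RNAs kept), the fold of the stretch, most pair counts and the fit without the 10 most abundant features (96 calls) were chosen after seeing the data. Across 14 alternative fits, total calls were within 1.5 times the main 95 except with DESeq2, which gave 551 calls, 289 higher, 262 lower, 137 over 2-fold, 516 outside the stretch and 45 neighbouring pairs. The cause was not tested. A minimum of 10 CPM in 3 libraries gave 59 higher, 103 outside the stretch and 1 list called by camera, DNA replication and repair (adjusted p = 0.0470, and adjusted p = 0.599 with an estimated correlation). That list was also called without PM replicate 3 (adjusted p = 0.0181, and 0.834 with an estimated correlation), and its camera adjusted p ranged from 0.0181 to 0.856 over the settings. Fry called 1 list. Leaving out 1 library gave 0 to 1 lists, 74 to 92 calls (26 to 38 higher, 47 to 60 lower), 47 to 64 over 2-fold, 47 to 62 outside the stretch, and 14 to 21 neighbouring pairs against the main 22, with 14 without PM replicate 3. An adjusted p under 0.01 left 68 calls.

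The numbers of the replicates do not pair the libraries: correlations of deviations between same-numbered libraries were -0.014, -0.053 and -0.017 across features, and no library correlated best with its own number. With a replicate block, 64 features were called, 20 higher and 37 outside the stretch. The median log2 fold change of the stretch kept its sign in every fit, at -1.12 with library totals only and -1.11 to -1.04 without 1 library. Calls over 2-fold gave 9 neighbouring pairs and the stretch left out gave 5, fewer by construction. For lower genes at the ends, the odds ratio of 0.124 reversed to 4.41 once wider ends (4164 tags) held the stretch (Fisher's exact test, p = 9.33e-06 and 0.00172). For higher genes 0.613 turned to 2.61, and neither of these values passed 0.05 (Fisher's exact test, p = 0.271 and 0.0541). The share of the authors' calls also called here moved from 43.7% to 73.5% for over 2-fold calls. Read 2 gave a deduplicated share lower in SM by the same direction as read 1. Lists were not run with DESeq2, pseudocounts do not apply to counts, and the alternatives for hrdB were not run. Depth limits features of few counts, whose errors are widest.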

Other observations

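The tag-order gradient in this part and its test were chosen after the data were seen. Genes at the outer 20% of either end of the tag order had lower TPM than those in the middle in every library, and less so in SM. For genes of at least the median relative length, the log2 ratio of the median TPM of the ends to that of the middle was -0.31 ± 0.02 in PM and -0.23 ± 0.02 in SM (SD, n = 3), with all 3 SM libraries above all 3 PM libraries (exact permutation test, two-sided, p = 0.1, the smallest 3 against 3 allows). Shorter genes gave -0.25 ± 0.01 in PM and -0.15 ± 0.01 in SM (SD, n = 3; exact permutation test, p = 0.1).

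Of the 10 most abundant features, 9 had a fold change above 0 on the log2 scale in SM, with a median of 0.72, and 0 were called (edgeR, smallest adjusted p = 0.0676). Without SM replicate 3, whose 10 features took 10.6% of counts, the median was 0.31 and 1 was called.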
